A study of Mus musculus with 7 samples.

How the data were processed

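Gene expression was measured with 10x Visium, which captures RNA from a tissue section on an array of barcoded spots so that each count keeps its position. The sections came from the spinal cord of C57BL/6 mice. Of the 7 libraries, 4 are labelled as spinal cord injury subjected to autonomic dysreflexia (SCI_AD) and 3 as spinal cord injury alone (SCI). Autonomic dysreflexia is a sudden rise in blood pressure that stimuli below a spinal injury can trigger. The series' design text describes young, old and treated old mice in groups of 3, whereas no sample label gives an age or a therapy, so the treatment label alone set the groups. The sample titles are a number and a letter, which may be a slide and a capture area, although the labels do not say so. Title numbers 1 and 2 hold 1 SCI_AD library each. Number 3 holds SCI_AD 3 and SCI 1, and number 4 holds SCI_AD 4, SCI 2 and SCI 3. The labels also call the material nuclei and nuclear RNA, which differs from the tissue sections that the protocol describes.

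The deposited matrices hold raw UMI counts (unique molecules) per gene and spot, for spots over tissue. Space Ranger 2.1.1 and Seurat 4 with the build GRCm39 are named in the submitters' processing notes, whereas the matrix header, per the file headers, names Space Ranger 3.0.0. Which steps Seurat performed is not given in the sources used here. A deposited table per library gives each gene's Moran's I, a score of spatial autocorrelation that is high where neighbouring spots have similar levels, with an adjusted p-value and the gene's count. The normalisation behind that score is not given in the sources used here. These tables' counts were checked to equal the row sums of the matrices. The deposited p-values, the image scale factors and any mapping of animals to sections were not used here. Gene names are those the files pair with their identifiers, over 32285 genes.

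The array holds 3 separate pieces of tissue in each library. Spots with under 500 UMIs were dropped, which kept 23276 of 25133. The kept spots were scaled to 10000 UMIs and log-transformed, and 2000 variable genes were centred and scaled within each library. Immediate early, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes were left out of that choice. A k-means clustering with 8 clusters and 10 starts was run on 20 principal components. A cluster took the name of the tissue class whose fixed marker genes had the highest mean log2 fold over the other spots, at a minimum of 0.5, with at least 3 detected markers and 1 marker among its 10 leading genes. A grey matter cluster was called superficial dorsal horn where its 10 leading genes held more markers of it than pan-neuronal and synaptic ones. For the cluster so named these numbers were 2 and 1. The markers were fixed beforehand, but the naming rule was set after the clusters were seen and changed while the code was written. This came before any test between the groups within a region. A cluster's leading genes define it, so their high level in it is not a result. Some of them are still reported in other comparisons of the same regions. These include Sprr1a, Gal and Nefl near the lesion in remaining grey matter, Eln in meninges and nerve roots and Mmp12 in lesion regions. The 2 clusters named as lesion together formed the lesion regions, and the one led by Cd36 and Mmp12 was the lesion core.

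The library was the replicate. Counts were summed per library over all kept spots and over each region. They were tested with edgeR 4.0.16 (TMM factors, its expression filter, quasi-likelihood test) with Benjamini-Hochberg adjustment at 0.05. The test of whether a change differed between remaining grey matter and white matter used a region by group interaction with the library as a block. Lists of genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. There were 35 lists, 34 of which had at least 5 tested genes in whole sections. The Moran's I of genes with at least 500 counts in every library was tested with limma. DESeq2 1.42.0 was the second tool for counts. Single values per library were compared by a two-sided exact permutation test over the 35 splits of the libraries into 4 and 3, whose smallest possible p is 0.0286. The share of grey matter UMIs from 43 immediate early genes, all found, was 1 such value. Fos was also counted after every spot was thinned to 1000 UMIs. The p-values measure only the spread between these libraries, which may be technical. How many animals a library holds is not given in the sources used here.

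The groups, tests, gene lists, markers and most alternatives were set before the data were examined. So was the rule for named genes. It takes genes that pass the adjusted threshold, reach a mean of 5 CPM (counts scaled by library size) and have no overlap between the groups' libraries, and from these the 12 largest changes each way in whole sections and 5 each way in a region. Where none passes, it takes the 5 each way with the smallest p. It adds a few fixed genes and the leading members of described lists. Some genes that the rule names are not reported here. The comparison of lesion regions between groups was added after the data were seen. So was the comparison of spots near and far from the lesion, which compares spots at most 8 and at least 16 spot spacings from a core spot with at least 3 core neighbours, with the library as a block. It was first run on both grey matter regions together. There the superficial dorsal horn made up 2.2% to 45.5% of the near spots and 46.4% to 67.9% of the far spots, so the comparison was restricted to remaining grey matter, and the first version was kept as an alternative.

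The alternatives covered other size factors, no filter on low counts, a minimum of 1000 UMIs per spot, all spots, 6 or 10 clusters, no scaling within library, thinned totals, other distances, the title number as a block and leaving out each library. In these, a count of genes was called the same when within 1.5 times the reported count. A named gene was called reversed where its change passed the test in either setting and the signs were opposite, and a list only where both had passed.

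The code was tested on simulated counts with the real means and library sizes and 200 changed genes. In whole sections it recovered 9.1%, 71.6% and 87.9% of genes changed 1.5, 2 and 3 times. In remaining grey matter these shares were 16.7%, 64.2% and 93.9%, and in white matter 35.8%, 76.1% and 100.0%. The libraries hold 13950204 to 36908298 UMIs. At these settings a change of 1.5 times between the groups would mostly have been missed.

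Software was R 4.3.3 and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0 and Matplotlib 3.10.9.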

Results

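Gene expression was mapped in sections of injured spinal cord from C57BL/6 mice with 10x Visium, in which each count keeps its place on an array of spots. Of the 7 libraries, 4 are labelled as spinal cord injury subjected to autonomic dysreflexia (SCI_AD) and 3 as the injury alone (SCI). Dysreflexia is a sudden rise in blood pressure triggered from below the injury. Matching pieces of tissue leave open that libraries of both groups share cords. In that case the tests between the groups do not compare independent libraries. The SCI_AD libraries 1 to 4 held 36908298, 13950204, 20366386 and 22596927 UMIs, and the SCI libraries 1 to 3 held 30181418, 20906100 and 33491119. The median per spot ran from 1769 UMIs in SCI_AD 2 to 8851.5 in SCI_AD 1. Mitochondrial transcripts made up 11.4% ± 1 of the UMIs in SCI_AD (SD, n = 4) and 11% ± 0.0656 in SCI (SD, n = 3), with a two-sided exact permutation p of 0.514. Xist, the RNA that silences an X chromosome in females, was at 0.331 CPM in the middle piece of tissue in SCI_AD 3 and 0.507 CPM in that of SCI 1, against 18.7 to 50 CPM in the other 19 pieces.

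Spots fell into 8 clusters, 6 of which took the name of a tissue class. The lesion core was led by Cd36 and Mmp12, genes of lipid uptake and matrix breakdown in macrophages, and a lesion border was led by Gpnmb, Klk8 and Lyz2. The superficial dorsal horn, where pain and touch signals enter, was led by Vsnl1, Snap25, Sst and Tac2. The remaining grey matter was led by Sprr1a and by the neurofilament genes Prph and Nefh, and also held Chil1 among its leading genes. White matter was led by myelin genes such as Gjb1 and Mog, and the meninges and nerve roots by Sfrp4, Igfbp6 and Eln. A cluster of 3659 spots with a median of 1745 UMIs and another of 2838 spots led by Ccn5 and C3 stayed unnamed. With 6 clusters 81.2% of spots kept their region, with 10 clusters 85.8%, and without scaling within the library 70.6%. The superficial dorsal horn depended on these choices: it held 11% to 17.8% of the spots per library, but 1.49% to 6.38% with 10 clusters and 1.08% to 9.04% without scaling, where remaining grey matter held more in every library.

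**Figure D1:**
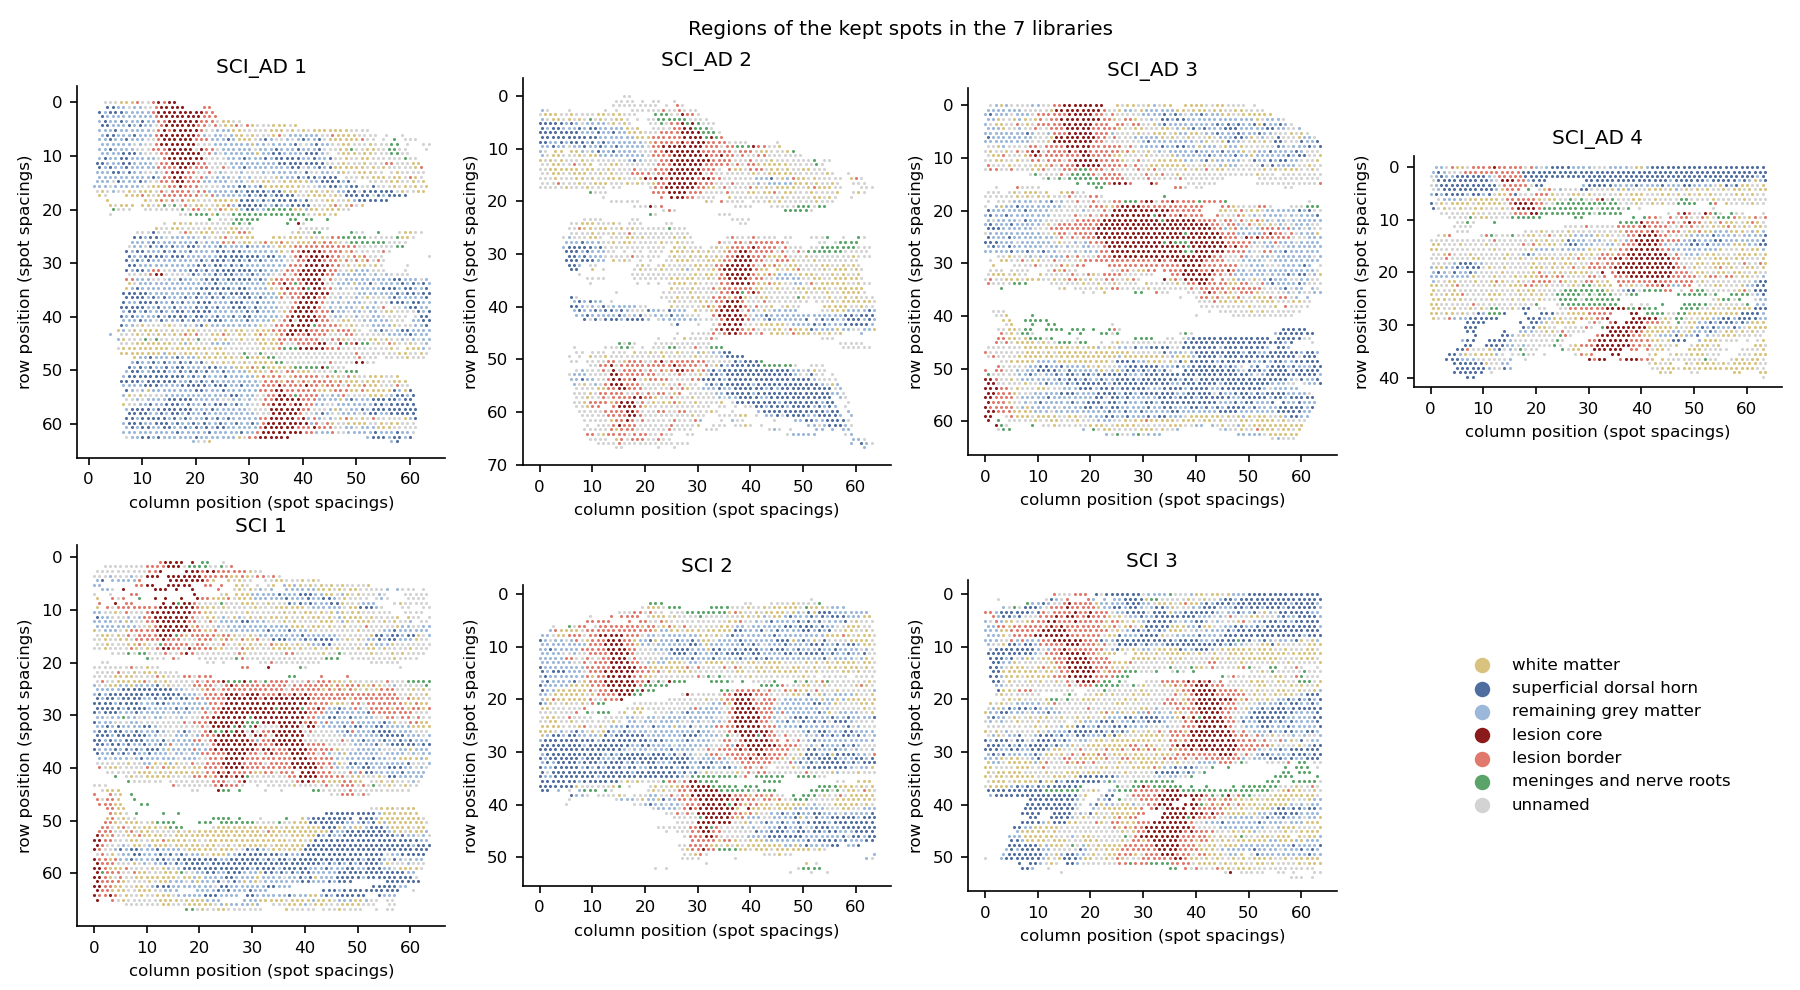
Spots of the 7 libraries at their array positions (column and row), coloured by region. Each library holds 3 separate pieces of tissue, and the lesion regions form patches within them.

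The shares of spots per region answered whether dysreflexia went with a different makeup of the sections. Lesion regions held 19.2% ± 2.29 of the spots in SCI_AD (SD, n = 4) and 20.4% ± 2.53 in SCI (SD, n = 3), with an exact permutation p of 0.514. The superficial dorsal horn held 14.1% ± 2.14 and 16.4% ± 1.73, with an exact p of 0.171. For remaining grey matter the shares were 17.9% ± 9.46 and 19.2% ± 4.68, for white matter 14% ± 3.03 and 15.2% ± 2.71, and for meninges and nerve roots 3.84% ± 2.32 and 3.68% ± 1.21. The unnamed spots differed most, at 31% ± 8.64 and 25.1% ± 0.973 (exact p = 0.343), with 22.6% to 42.4% over the SCI_AD libraries. Adjusted over the 6 classes of spots, the permutation p ran from 0.856 to 0.914, and the smallest p the 35 splits allow is 0.0286. SCI_AD 4 stood apart in meninges and nerve roots with 7.32%, against 2.59% to 2.79% in the other 3 SCI_AD libraries.

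Whole sections were compared to ask which genes dysreflexia changed anywhere in the cord. Lst1, a gene of leukocytes in the histocompatibility region, was higher in every SCI_AD library than in any SCI library, at 37.7 ± 4.27 CPM (SD, n = 4) against 25.6 ± 3.47 (SD, n = 3). Gpr17, a receptor of oligodendrocyte precursors on the way to myelination, was lower, at 48.4 ± 2.13 against 65.4 ± 9.43 CPM, and so was Hpgd, which breaks down prostaglandins, at 54.3 ± 5.14 against 72.7 ± 1.74 CPM. None of these 3 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where each had an adjusted p of 1. Their log2 fold changes were 0.56 ± 0.12 (SE) for Lst1, -0.43 ± 0.11 for Gpr17 and -0.42 ± 0.1 for Hpgd. Among the 15991 genes tested edgeR called 0, with 330 at an unadjusted p under 0.05, and DESeq2 also called 0. The other genes with the smallest p were Fhl3, Ccdc73, Gm4951 and Gm46224 on the higher side and Ucn, Gm20627 and Gm19412 on the lower side. Fos had a log2 fold change of -0.29 ± 0.11, Gfap of -0.1 ± 0.15 and Mbp of 0.07 ± 0.26, none of them passing.

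Genes of fibroblasts and meninges, of antigen presentation and of blood leukocytes lay mostly on the higher side in whole sections, although none of them passed alone. All 18 measured fibroblast genes were positive, as were 13 of 16 genes of antigen presentation and complement, 18 of 19 interferon genes, 14 of 16 leukocyte genes and 9 of 14 genes of pericytes and smooth muscle. Camera at the preset correlation called 12 of 34 lists, with adjusted p of 7.74e-07 for fibroblasts, 2.91e-06 for antigen presentation, 1.01e-05 for leukocytes, 0.000302 for interferon genes and 0.0204 for pericytes. With an estimated correlation it called 0, at an adjusted p = 0.624 for these 5 lists, and 26 of the 35 splits of the libraries gave as many lists at the preset correlation. Without SCI_AD 4 the fibroblast list had an adjusted p of 0.0546. Col1a1, a collagen of scar fibroblasts, had a log2 fold change of 0.57 ± 0.25 (SE), with 369, 580, 682 and 880 CPM in SCI_AD 1 to 4 and 405 to 440 CPM in SCI. H2-Ab1 and Cd74, which load peptides for display to T cells, had 0.64 ± 0.19 and 0.51 ± 0.18. The leukocyte gene Igkc, an antibody light chain, reached 30.4 CPM in SCI_AD 2 and 15.9 CPM in SCI_AD 4, against 4.25 and 1.19 CPM in the other SCI_AD libraries and 0.588 to 1.54 CPM in SCI. The mitochondrially encoded list was also higher, with 12 of 13 genes positive (adjusted p = 4.32e-06, and 0.624 with an estimated correlation). Its gene mt-Atp8 stood at 225 and 197 CPM in SCI_AD 1 and 2, at 82.5 and 105 CPM in SCI_AD 3 and 4, and at 65.4 to 80.2 CPM in SCI. Nuclear genes of the respiratory chain (16 of 21 positive, adjusted p = 0.0232, and 0.877 with an estimated correlation) and inflammatory cytokines (16 of 19 positive, adjusted p = 0.0235, and 0.645 with an estimated correlation) were the other lists on the higher side.

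Oligodendrocyte precursor genes shifted down, with 1 of 12 positive, a median log2 fold change of -0.16 and a camera adjusted p of 0.00014 (0.624 with an estimated correlation). Gpr17 passed when adjusted over the list alone. The cholesterol synthesis list had 3 of 20 genes positive (adjusted p = 0.00859, and 0.733 with an estimated correlation), with Idi1 at a log2 fold change of -0.29 ± 0.11 (SE). Cholinergic and motor neuron genes had 3 of 15 positive (adjusted p = 0.0308, and 0.643 with an estimated correlation). Sensory ganglion genes had 1 of 5 positive (adjusted p = 0.0214, and 0.624 with an estimated correlation), led by Sncg, a synuclein of sensory neurons, at a log2 fold change of -0.38 ± 0.16. The other 22 lists had camera adjusted p from 0.0716 to 0.724. Among them, excitatory neurons had an upward test and a median of -0.03, endothelial cells a downward test and a median of 0, and erythrocytes a downward test and a median of 0.11.

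Immediate early genes, which neurons switch on when they fire, were compared in grey matter because dysreflexia is driven by spinal circuits. Fos, Arc, Egr1 and 40 further genes together made up 0.0965% ± 0.0122 of grey matter UMIs in SCI_AD (SD, n = 4) and 0.114% ± 0.0142 in SCI (SD, n = 3). The difference of -0.0171 percentage points had a two-sided exact permutation p of 0.171, and it was -0.00919 without SCI 2 (exact p = 0.467) and -0.0089 over all spots (exact p = 0.286). After every spot was thinned to 1000 UMIs, Fos was seen in 1.39% ± 0.324 of grey matter spots in SCI_AD and in 2.49% ± 0.69 in SCI, with an exact p of 0.0571. Fos in lesion spots, thinned alike, was seen in 1.38% to 3% per library. The share in grey matter was above that in lesion spots in SCI 2 (2.86% against 2.46%) and SCI 3 (2.91% against 2.71%) and below it in the other 5 libraries. Without thinning the Fos shares were 12.1% ± 4.5 and 15.2% ± 4.96 (exact p = 0.457), at medians of 5079.5 to 12068.5 UMIs per grey matter spot.

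**Figure D2:**
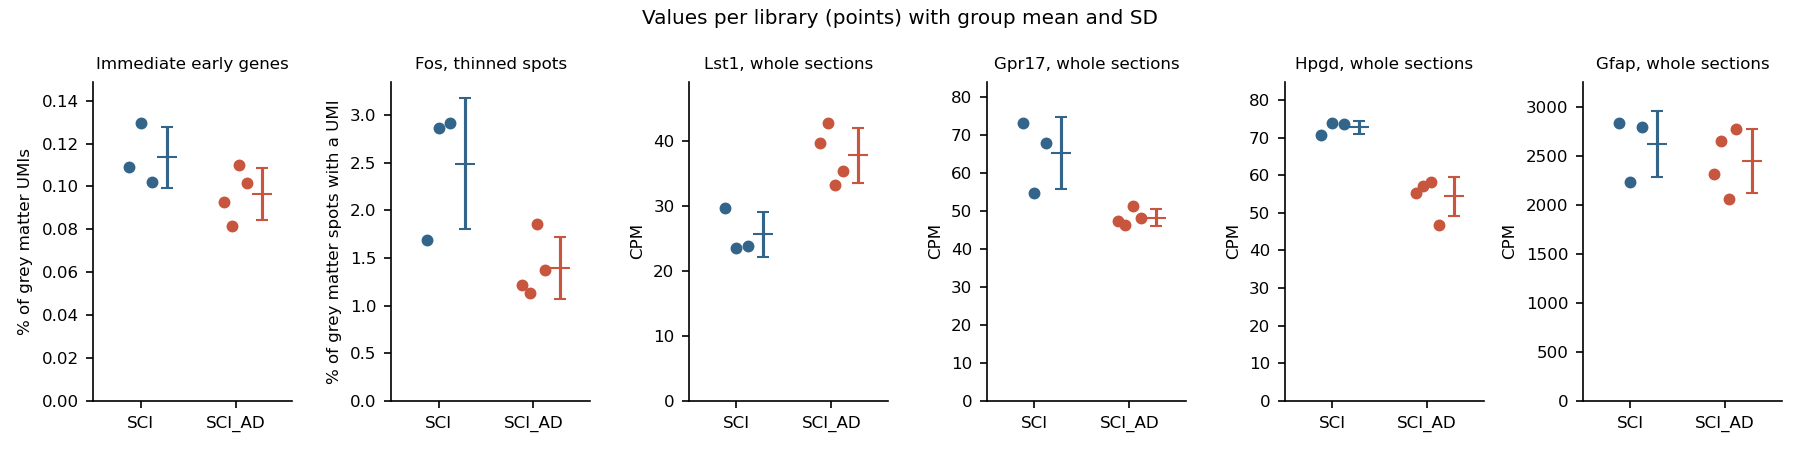
Values per library (points) with the group mean and SD, for the immediate early gene share and thinned Fos share of grey matter (%) and for Lst1, Gpr17, Hpgd and Gfap in whole sections (CPM). Lst1, Gpr17 and Hpgd do not overlap between the groups, whereas Gfap does.

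In remaining grey matter, which holds the motor and premotor circuits, the gene with the smallest p was Glra1, a glycine receptor subunit of inhibitory synapses. It stood at 15.3 ± 6.93 CPM in SCI_AD (SD, n = 4) and 5.43 ± 1.1 CPM in SCI (SD, n = 3), a log2 fold change of 1.54 ± 0.34 (SE). Kcna1, a potassium channel of axons, had a log2 fold change of 0.97 ± 0.22, and Zfhx3, a homeobox gene of long-range projecting neurons, 0.63 ± 0.16. Gpr17 was lower here too, at 37.4 ± 4.55 against 55.7 ± 11.6 CPM. All had an adjusted p of 1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which called 0 of 13312 genes, with 287 at an unadjusted p under 0.05, and DESeq2 called 0. Rab26os was also among the 5 with the smallest p on the higher side, and Hrct1, Osgin1, 1810055G02Rik and Traf7 on the lower side.

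Astrocyte and interferon genes were shifted up in remaining grey matter, with 14 of 14 and 18 of 19 genes positive (camera adjusted p = 0.000174 and 5.12e-06, and 0.945 and 0.731 with an estimated correlation). Sox9, a transcription factor of astrocytes, had a log2 fold change of 0.42 ± 0.17 (SE), and Cxcl10, a chemokine induced by interferon, 1.21 ± 0.42. The immediate early list was shifted down, with 12 of 35 positive (adjusted p = 0.00684, and 0.731 with an estimated correlation), as were oligodendrocyte precursors with 3 of 12 (adjusted p = 0.0422, and 0.945 with an estimated correlation). Inflammatory cytokines (11 of 14 positive, adjusted p = 0.00323), V2a and zinc finger homeobox neurons (9 of 10, adjusted p = 0.0152) and mitochondrially encoded genes (13 of 13, adjusted p = 3.59e-07) were shifted up. For these 3 lists the adjusted p was 0.731 with an estimated correlation. Zfhx3 passed when adjusted over its list alone.

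The superficial dorsal horn is where pain and touch signals enter, but the region named so here may also hold other grey matter. With 10 clusters it shrank to 1.49% to 6.38% of the spots per library. Snap25 and Vsnl1 then led a part of remaining grey matter. In the region with 8 clusters Gadd45g, an early stress response gene, stood at 42.6 ± 2.87 CPM in SCI_AD (SD, n = 4). In SCI it stood at 57.9 ± 5.86 CPM (SD, n = 3). Acvr1, a receptor for bone morphogenetic proteins, was lower as well, with a log2 fold change of -0.56 ± 0.16 (SE), and SCI_AD 2 lay apart at 10.8 CPM against 14.2 to 14.3 CPM in the other SCI_AD libraries. Sprr1a and Gap43, which mark axon growth, had log2 fold changes of -0.71 ± 0.27 and -0.28 ± 0.12. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 13465 genes passed, with 305 at an unadjusted p under 0.05, and by DESeq2 0. Immediate early genes were shifted down with 12 of 38 positive (camera adjusted p = 4.65e-05), as were axon growth genes with 5 of 18 (adjusted p = 0.00563) and erythrocyte genes with 1 of 7 (adjusted p = 0.0456), each at 0.905 with an estimated correlation. Astrocyte genes (13 of 14 positive, adjusted p = 0.00563), nuclear respiratory chain genes (18 of 21, adjusted p = 0.00563) and mitochondrially encoded genes (13 of 13, adjusted p = 1.42e-06) were higher, also at an adjusted p = 0.905 with an estimated correlation. Of the mitochondrially encoded genes 3 passed when adjusted over the list alone.

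In white matter Gpr17 had the smallest p of all genes, at 60.9 ± 9.06 CPM in SCI_AD (SD, n = 4) and 98.3 ± 13.4 in SCI (SD, n = 3), with 47.4 CPM in SCI_AD 2 against 64.4 to 66.4 CPM in the other SCI_AD libraries. The ribosomal protein genes Rps27, Rps28 and Rpl37a were higher, Rps27 at 789 ± 172 against 467 ± 39.4 CPM. Rps27 stood at 855 and 996 CPM in SCI_AD 1 and 2, whose title numbers hold no SCI library. It stood at 608 and 697 CPM in SCI_AD 3 and 4. Slc5a7, the choline transporter of motor axons, had a log2 fold change of -1.06 ± 0.27 (SE), and Midn, which takes short-lived proteins to the proteasome, one of 1.04 ± 0.2. Ribosomal protein genes as a class made up 9.33% ± 0.493 of all UMIs in SCI_AD and 8.94% ± 0.26 in SCI, with an exact permutation p of 0.371. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.303 for Gpr17, Rps27 and Midn. Of 12095 genes 0 passed and 638 had an unadjusted p under 0.05, whereas DESeq2 called 20. Without SCI_AD 3 edgeR called 34.

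Schwann cell genes gave a further difference in white matter: Prx, a scaffold protein of these cells, had a log2 fold change of 1.2 ± 0.41 (SE), and 6 of 7 genes of the list were positive (camera adjusted p = 0.0112, and 0.254 with an estimated correlation). Oligodendrocyte precursor genes were shifted down with 4 of 12 positive (adjusted p = 0.0125, and 0.254 with an estimated correlation). The V2a and zinc finger homeobox list, led by the widely expressed Tcf4 at a log2 fold change of 0.38 ± 0.11, had 6 of 6 positive (adjusted p = 9.33e-05, and 0.254 with an estimated correlation). Mitochondrially encoded genes had 12 of 13 positive (adjusted p = 3.92e-06, and 0.551 with an estimated correlation). Genes adjusted over the list alone passed 2 times among Schwann cells, 1 time among precursors and 3 times in each of the last 2 lists. Cholinergic genes had 2 of 11 positive (adjusted p = 0.0049, and 0.458 with an estimated correlation), and erythrocyte genes 1 of 6 (adjusted p = 0.0049, and 0.551 with an estimated correlation). Endothelial genes had 2 of 14 positive (adjusted p = 0.025, and 0.599 with an estimated correlation), and neuropeptides 3 of 13 (adjusted p = 0.0327, and 0.682 with an estimated correlation).

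In the meninges and nerve roots Eln, which encodes elastin of vessel walls and meninges, stood at 1931 ± 527 CPM in SCI_AD (SD, n = 4) and 696 ± 372 in SCI (SD, n = 3), a log2 fold change of 1.46 ± 0.3 (SE). Kcnj15, a potassium channel, stood at 119 ± 13.2 against 49.8 ± 15.2 CPM, and Dio2, which activates thyroid hormone, had a log2 fold change of 1.37 ± 0.29. Cadm3, an adhesion protein of axons and glia, was lower at 30.2 ± 1.42 against 56.1 ± 0.355 CPM. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.182 for Kcnj15 and 0.306 for Eln. Of 8656 genes 0 passed and 494 had an unadjusted p under 0.05. DESeq2 called 5, which were Eln, Cdkn1c, Dio2, Kcnj15 and Igfbp5, the last named after its values were seen. Comp was also among the 5 with the smallest p on the higher side, and Tnc, Amz1, Gadd45g and Id4 on the lower side.

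Fibroblast genes were higher in this region, with 17 of 18 positive, a camera adjusted p of 1.75e-05 (0.26 with an estimated correlation) and 5 genes passing when adjusted over the list alone, and Schwann cell genes were lower, with 0 of 12 positive (adjusted p = 0.00063, and 0.447 with an estimated correlation). Cemip, which breaks down hyaluronan, led the fibroblast list with a log2 fold change of 0.82 ± 0.21 (SE), and Ncmap, a protein of compact peripheral myelin, the Schwann cell list with -0.73 ± 0.27. Endothelial genes (13 of 14 positive, adjusted p = 0.00559, and 0.54 with an estimated correlation), Hox genes (9 of 12, adjusted p = 0.00559, and 0.26 with an estimated correlation) and mitochondrially encoded genes (12 of 12, adjusted p = 9.15e-05, and 0.58 with an estimated correlation) were higher. Homeostatic microglia (1 of 11 positive, adjusted p = 0.00671) and oligodendrocyte precursors (2 of 10, adjusted p = 0.0433) were lower, both at 0.447 with an estimated correlation. So were phagocytic myeloid genes (4 of 21, adjusted p = 0.00731) and myelin (3 of 16, adjusted p = 0.0162), both at 0.707 with an estimated correlation, and astrocytes (4 of 13, adjusted p = 0.0377, and 0.667 with an estimated correlation).

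The lesion regions, a comparison added after the data were seen, were used to ask whether leukocyte genes differed inside the lesion. Ccr2, the receptor that draws monocytes into tissue, had a log2 fold change of 0.88 ± 0.26 (SE) there, H2-Ab1 of 0.85 ± 0.25 and Mmp12, an elastase of macrophages, of 0.72 ± 0.24. Fcgr4, an antibody receptor of myeloid cells, stood at 99.1 ± 8.62 CPM in SCI_AD (SD, n = 4) and 68.6 ± 10.3 in SCI (SD, n = 3). Grb14, an adaptor of insulin signalling, was lower at a log2 fold change of -0.62 ± 0.12, with SCI_AD 1 apart at 70.1 CPM against 53.1 to 55.6 CPM in the other SCI_AD libraries, and Hpgd and F3, the trigger of clotting, had -0.66 ± 0.15 and -0.57 ± 0.13. All had an adjusted p of 0.967 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which called 0 of 13602 genes, with 644 at an unadjusted p under 0.05, whereas DESeq2 called 20. Leukocyte genes were positive in 11 of 11 (camera adjusted p = 2.19e-05) and antigen presentation genes in 13 of 16 (adjusted p = 1.22e-05), whereas oligodendrocyte precursor genes were positive in 0 of 12 (adjusted p = 5.91e-06). Each of these 3 had an adjusted p = 0.607 with an estimated correlation, and camera called 10 further lists at the preset correlation and 0 with an estimated one.

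The interaction of region and group asked whether dysreflexia acted differently in remaining grey matter and white matter. Cxcl10, the chemokine that interferon induces, had the smallest p, with a change 1.16 ± 0.25 (log2, SE) higher in grey matter than in white matter, followed by Ifit3b, a further interferon gene, at 0.8 ± 0.2 and Calb2, a calcium buffer of interneurons, at 0.74 ± 0.2. Cmss1, a gene of ribosome assembly, and Sgk1, a kinase induced by stress hormones, had changes of -1.07 ± 0.26 and -0.46 ± 0.15 relative to white matter. Each had an adjusted p of 1 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which called 0 of 13564 genes, with 372 at an unadjusted p under 0.05, and DESeq2 was not run on it.

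Spatial autocorrelation was compared between the groups through the deposited Moran's I. Lyz2, the lysozyme of macrophages, was the most patterned gene with a mean score of 0.739 ± 0.0997 (SD, n = 7), followed by Spp1, a secreted phosphoprotein of phagocytes, at 0.727 and the ferritin gene Ftl1 at 0.718. Gpnmb and Ctsd, both of lysosomes, had 0.705 and 0.693. Limma called 0 of 3968 genes between the groups, with 103 at an unadjusted p under 0.05, and no other tool was run on these scores.

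Remaining grey matter near the lesion core held more RNA of phagocyte genes than that far from it. This comparison over all 7 libraries was added after the data were seen. Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, rose by a log2 fold change of 2.6 ± 0.07 (SE), from 147 ± 58.7 CPM far away to 876 ± 320 CPM near the lesion (SD, n = 7), and was higher near it in 7 of 7 libraries. Lyz2 rose by 2.42 ± 0.07, and Cd5l, a survival factor of macrophages, and Atp6v0d2, a proton pump subunit of phagocytes, by 2.87 ± 0.25 and 2.78 ± 0.29. Itih3, a stabiliser of the matrix made by astrocytes, fell with a log2 fold change of -1.51 ± 0.1, and Ptgds, the prostaglandin D synthase of glia, with -1.1 ± 0.07, from 1198 ± 159 to 559 ± 81.5 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 5.28e-20 for Gpnmb and 9.01e-12 for Itih3. Of 11683 genes 1050 rose and 982 fell, and DESeq2 called 1257 in all. The near set held 48 to 308 spots per library and the far set 102 to 458. These rankings take only genes of at least 5 CPM without overlap between the near and far values of the libraries. The other such genes with the largest rises were Hpse, Clec4d, Apoc4, Ms4a7, Acp5, Clec12a, Msr1 and Wfdc17. Among the largest such falls were Tlcd1, Scrt1, Ntsr2, Cldn10 and Msmo1. Some genes with overlap fell further, such as the haemoglobin gene Hbb-bt (-2.55 ± 0.275) and the interferon gene Ifit1 (-1.54 ± 0.232). The lesion border, which Gpnmb, Lyz2, Cd5l, Atp6v0d2 and Wfdc17 mark most strongly, was not part of either set of spots. Of the genes that rose, 25.2% had a higher CPM in near grey matter than in the lesion regions. Gpnmb and Lyz2 were higher in the lesion, so spread of their RNA from lesion spots remains open.

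Genes of injured and regrowing neurons rose near the lesion, whereas a neurofilament gene and an astrocyte transporter gene fell. Sprr1a, which injured neurons express as their axons regrow, rose by a log2 fold change of 1.74 ± 0.13 (SE), Atf3, the injury transcription factor, by 1.18 ± 0.1 and Gap43 by 0.63 ± 0.07. The neuropeptide gene Npy rose by 1.82 ± 0.14, Penk by 1.37 ± 0.17 and Gal by 1.16 ± 0.15. Nefl, a neurofilament, fell with -0.5 ± 0.09, and Slc6a11, a GABA transporter of astrocytes, with -1.02 ± 0.11. Gpr17, the precursor gene, rose by 0.98 ± 0.13, from 34.2 ± 9.6 CPM far away to 64.1 ± 25.2 CPM near the lesion (SD, n = 7). Gfap had a log2 fold change of -0.17 ± 0.09 and did not pass, and it took the opposite sign, at 0.38, when both grey matter regions were pooled. Fos did not pass either, at -0.14 ± 0.17, whereas Egr1 and Junb rose by 1.04 ± 0.14 and 0.62 ± 0.14.

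Phagocytic myeloid genes rose in 19 of 21 cases in remaining grey matter, with a median log2 fold change of 1 and a camera adjusted p of 0.00517 with an estimated correlation (20 passed when adjusted over the list alone). Axon growth genes rose in 14 of 18 (adjusted p = 0.00579 with an estimated correlation, 15 adjusted over the list alone), and antigen presentation genes in 9 of 16 (adjusted p = 0.00842 with an estimated correlation, 11 adjusted over the list alone), led by H2-D1. Astrocyte genes fell in 12 of 14 and mitochondrially encoded genes in 13 of 13, with medians of -0.58 and -0.57, and immediate early genes rose in 13 of 29. These 3 lists and homeostatic microglia had an adjusted p = 0.0708 with an estimated correlation. Cholesterol synthesis genes fell in 17 of 20, with a median of -0.66 (adjusted p = 0.144 with an estimated correlation), and interferon genes in 12 of 18 (adjusted p = 0.499 with an estimated correlation). Camera called 20 of 32 lists at the preset correlation, 3 with an estimated one, and fry called 17. The hypoxia list had a downward test and a median of 0.08, and inflammatory cytokines had an upward test, a median of 0.1 and a mean of -0.04.

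**Figure D3:**
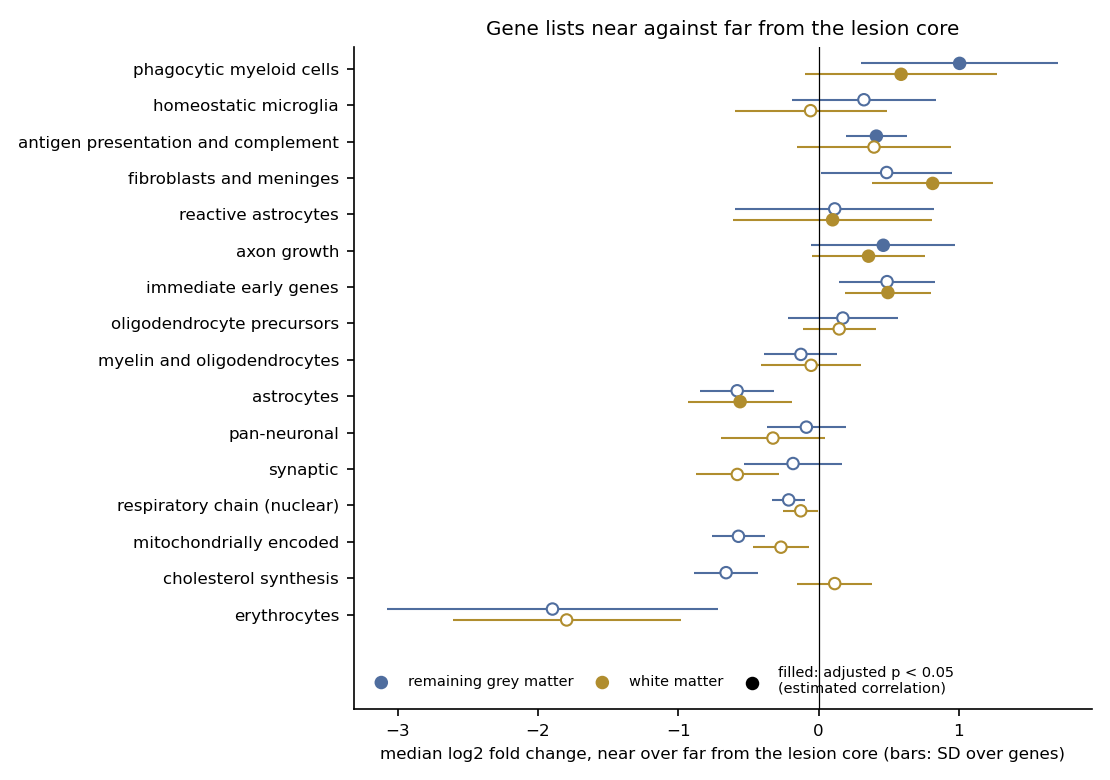
Median log2 fold change (near over far from the lesion core) of 16 gene lists in remaining grey matter and white matter, with bars for the SD over genes and filled points where the adjusted p was under 0.05 with an estimated correlation. Phagocytic myeloid genes have the highest median in remaining grey matter, and erythrocyte genes the lowest in both regions.

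White matter near the lesion shared the phagocyte genes and was led by Klk8, a protease that cleaves myelin and adhesion proteins. Klk8 rose by a log2 fold change of 3.1 ± 0.13 (SE), from 42.3 ± 18.7 CPM far away to 396 ± 117 CPM near the lesion (SD, n = 7). In remaining grey matter Klk8 also rose, by 0.64 ± 0.15, and the difference between the regions was not tested. Spp1 rose by 1.94 ± 0.08, Lyz2 by 1.88 ± 0.09 and Serpina3n, a protease inhibitor of reactive astrocytes, by 1.57 ± 0.13. Ppp1r1b, a phosphatase regulator, fell with a log2 fold change of -2.09 ± 0.25, Agt, the angiotensin precursor of astrocytes, with -1.06 ± 0.07 and Gfap with -0.22 ± 0.06. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 2.85e-23 for Klk8 and 1e-08 for Ppp1r1b. Of 10053 genes 984 rose and 888 fell, and DESeq2 called 939 in all. Of the genes that rose, 36.3% had a higher CPM in near white matter than in the lesion regions. Klk8, Spp1 and Lyz2 are also leading genes of the lesion border, which was not compared.

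Phagocytic myeloid genes rose in 17 of 21 cases in white matter, with a median log2 fold change of 0.59 (camera adjusted p = 0.0425 with an estimated correlation), and fibroblast genes in 11 of 15, with a median of 0.81 (adjusted p = 0.049 with an estimated correlation). Astrocyte genes fell in 12 of 14, with a median of -0.56 (adjusted p = 0.0257 with an estimated correlation). Immediate early genes rose in 10 of 26 (adjusted p = 0.0425), axon growth genes in 8 of 17 (adjusted p = 0.049) and reactive astrocyte genes in 5 of 14 (adjusted p = 0.049), each with an estimated correlation. Adjusted over the list alone, the genes passing numbered 17 for phagocytes, 11 for fibroblasts, 14 for astrocytes, 14 for immediate early genes, 11 for axon growth and 7 for reactive astrocytes. Camera called 12 of 32 lists at the preset correlation and 6 with an estimated one.

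Dysreflexia was then compared in how each gene differed near the lesion from far away. Uts2, the urotensin peptide gene of motor neurons, was higher near the lesion in SCI_AD, with a mean log2 near over far of 1.08 ± 0.5 (SD, n = 4), and lower in SCI, at -0.99 ± 0.52 (SD, n = 3). Calca, which encodes the peptide CGRP of motor and sensory neurons, had 0.44 ± 0.66 in SCI_AD and -1.12 ± 0.7 in SCI. Tac2, the neurokinin B gene of dorsal horn neurons, went the other way, with 13, 0, 1 and 15 UMIs near the lesion in SCI_AD 1 to 4 against 55, 1, 20 and 24 far away. In SCI 1 to 3 the near counts were 2, 32 and 97 UMIs against 1, 17 and 24 far away. The interaction in remaining grey matter was 1.95 ± 0.24 (log2, SE) for Uts2, 1.52 ± 0.28 for Calca and -3.76 ± 0.47 for Tac2, with adjusted p of 0.000111, 0.0449 and 0.000111 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These were the 3 genes called of 11683, with 512 at an unadjusted p under 0.05. When each library was left out Uts2 always passed, Tac2 was lost without SCI 3, and Calca passed only without SCI 2 or SCI_AD 4. At 6 and 12 spacings Tac2 alone was called, with Uts2 at an adjusted p of 1, and at 4 and 20 spacings or with both grey matter regions pooled Uts2 alone was. With a separate effect of zone for each title number, chosen after the results were seen, Uts2 kept its call and Calca and Tac2 lost theirs. At least as many genes were called by 13 of the 35 splits of the libraries. Cholinergic genes were positive in 11 of 12 (camera adjusted p = 1.7e-11, and 0.156 with an estimated correlation) and superficial dorsal horn genes in 3 of 15 (adjusted p = 6.01e-07, and 0.259 with an estimated correlation). With 10 clusters Calca and Uts2 led a part of remaining grey matter together with Prph, Slc5a7 and Slc18a3, and Tac2 led the superficial dorsal horn. Whether the near and far spots held different parts of the grey matter in the 2 groups was not tested. Camera called 15 of 32 lists at the preset correlation and 0 with an estimated one.

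Chil1, a chitinase-like protein of reactive astrocytes, was the gene called in white matter. Its call was lost at 4 and 20 spacings (adjusted p = 0.152), and also with a separate effect of zone for each title number. It had a mean log2 near over far of 0.77 ± 0.52 in SCI_AD (SD, n = 4) and -0.83 ± 0.49 in SCI (SD, n = 3), an interaction of 1.81 ± 0.25 (SE). Its adjusted p was 4.22e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 1 gene called of 10053, 423 at an unadjusted p under 0.05, and 19 of the 35 splits of the libraries giving as many. Serpina3n, Klk8, Lcn2 and Klk6, the last 2 named after their values were seen, were called beside Chil1 without SCI 1. Without SCI_AD 1 Chil1 was also called in remaining grey matter, at a log2 interaction of 2.11 (adjusted p = 0.00011). Camera called 5 of 32 lists at the preset correlation, among them pan-neuronal genes with 12 of 12 positive, and 0 with an estimated correlation (adjusted p from 0.436 to 0.571). Chil1 was also a leading gene of remaining grey matter. Whether near or far white matter spots held more grey matter in either group was not tested.

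**Figure D4:**
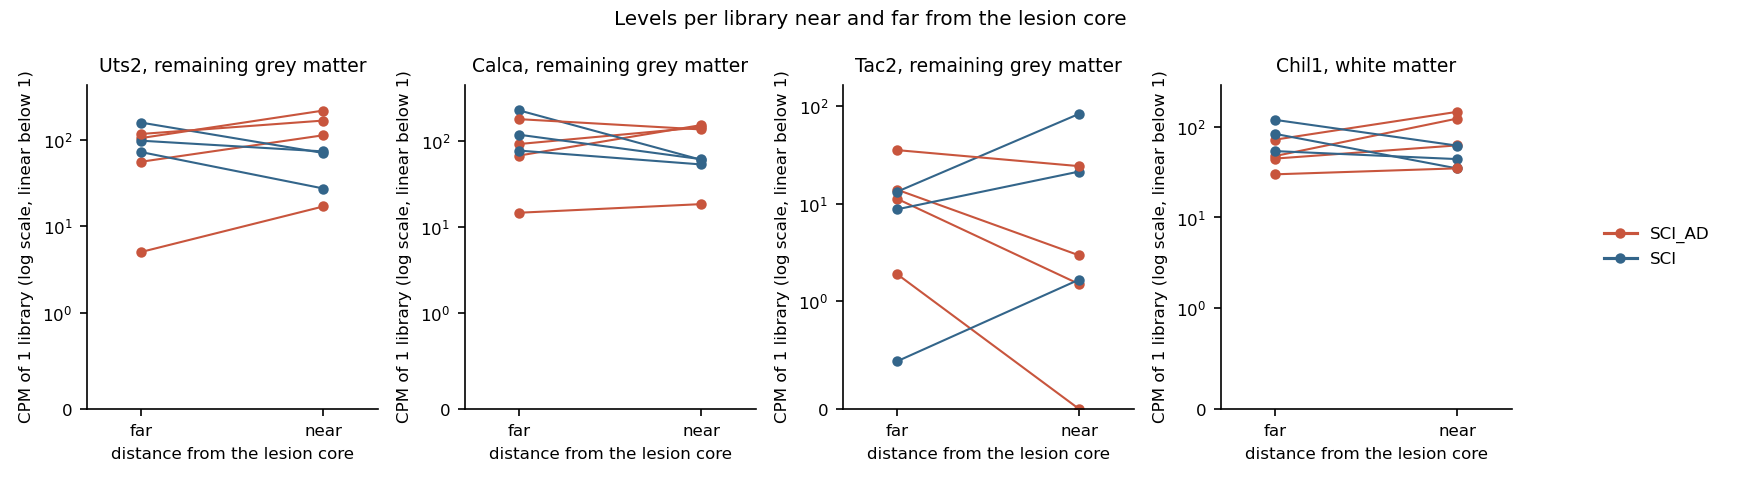
CPM of Uts2, Calca and Tac2 in remaining grey matter and of Chil1 in white matter, far from and near the lesion core, with 1 line per library on a log scale that is linear below 1. Uts2 and Chil1 go up towards the lesion in all 4 SCI_AD libraries and down in all 3 SCI libraries.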

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

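The comparisons near and far from the lesion, their tests of a difference between the groups and the comparison of lesion regions were chosen only after the data were seen, as was the test of splits for the first of these in remaining grey matter.

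A library far from the other 3 of the SCI_AD group was found for 4 of 80 values examined. Chance alone marks about 1 in 20 such groups, so this number points to nothing beyond chance. In meninges and nerve roots SCI_AD 4 held 7.32% of its spots, against 2.59% to 2.79% in the others. The level of Acvr1 in the superficial dorsal horn was 10.8 CPM in SCI_AD 2, against 14.2 to 14.3 CPM. Gpr17 in white matter stood at 47.4 CPM in SCI_AD 2, against 64.4 to 66.4 CPM, and lay on the side of the group difference. Grb14 in lesion regions stood at 70.1 CPM in SCI_AD 1, against 53.1 to 55.6 CPM.

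The difference between near and far from the lesion differed between the groups for 4 genes, by a test of the interaction itself. It was 1.945 (log2) for Uts2, 1.523 for Calca and -3.757 for Tac2 in remaining grey matter, and 1.811 for Chil1 in white matter. Chance cannot be excluded for these numbers of genes. In remaining grey matter 13 of the 35 splits of the libraries gave 3 or more genes, and the highest other split gave 13. In white matter 19 of the 35 splits gave 1 or more, and the highest other split gave 14.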

How the results depend on the processing

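The comparisons of lesion regions, of near and far spots and of their differences between groups, with all their alternatives, were chosen only after the data were seen, as were the pooling of both grey matter regions and the ependymal level as a covariate. Where an alternative changed a result, the cause was not tested unless its construction shows it.

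The counts of 0 genes changed held in whole sections, remaining grey matter and superficial dorsal horn under every alternative run, DESeq2 included, with 0 to 0 genes when each library was left out, and so did the 0 genes with a changed Moran's I. The immediate early share differed by -0.0229 to -0.00919 percentage points when each library was left out, the smallest without SCI 2, and by -0.0089 over all spots in place of grey matter. No share of spots passed. In white matter DESeq2 called 20 genes and the fit with no filter on low counts 78. Leaving out each library gave 0 to 34 there, with 34 without SCI_AD 3. In meninges and nerve roots DESeq2 called 5 genes and the fit with no filter 46. The range with each library left out was 0 to 3, with 3 without SCI_AD 3 (Igfbp5, Cdkn1c and Comp) and 2 without SCI 2 (Eln and Kcnj15). In lesion regions DESeq2 called 20 genes, and leaving out each library gave 0 to 0. The interaction of grey and white matter gave 0 to 1, with Hbb-bt called without SCI_AD 1. Igfbp5 and Hbb-bt are named after their values were seen.

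Title numbers were not taken as pairs, because a rule set beforehand asked for more than 0.1 in every correlation of whole libraries across groups within a number. These correlations were 0.066, -0.173 and 0.476. The best match in the other group had the same number for 2 of the 7 libraries (SCI 3 and SCI_AD 4). SCI_AD 1 and SCI_AD 2 could not match, as their numbers hold no SCI library. The white matter of pieces at the same position matched across groups for every such pair. It correlated at 0.473 for SCI_AD 3 and SCI 1, 0.251 for SCI 2 and SCI_AD 4, and 0.41 for SCI 3 and SCI_AD 4. These matching pieces leave open that libraries of a number share cords. In that case they are not independent, as the tests and splits take them to be. With the title number as a block, 1 gene was called in white matter (Col1a1), 2 in meninges and nerve roots (Krtdap and Cdkn1c) and 13 in lesion regions, and 0 in whole sections, remaining grey matter and superficial dorsal horn. With a separate effect of region or zone for each title number, chosen after the results were seen, the interaction of grey and white matter was called for 4 haemoglobin genes (Hba-a1, Hba-a2, Hbb-bs and Hbb-bt). The difference of near and far between groups was then called for 2 genes in remaining grey matter (Uts2 at a log2 of 1.74, adjusted p = 0.00499, and Chil1) and for 0 in white matter. Adjusted p was 0.424 for Calca, 0.24 for Tac2 and 0.106 for Chil1 in white matter. With the title number as a block 17 lists were called in whole sections, 7 of them shared with the 12 reported.

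Near the lesion in remaining grey matter 2032 genes were called, 1257 by DESeq2, 1294 at 4 and 20 spacings, 4712 with both grey matter regions pooled and 1558 to 2039 when each library was left out. In white matter 1872 were called, 939 by DESeq2 and 1502 to 1799 when each library was left out. Pooling mixes in dorsal horn spots, and with it Gfap (0.379), Mbp (0.34), Slc2a1 (0.086) and the myelin list (0.312) took the opposite sign. At 4 and 20 spacings Sparc (-0.283), Osmr (-0.046) and Mia (-0.048) did. The difference of near and far between groups in remaining grey matter was called for 3 genes, for 1 with both regions pooled (Uts2), 1 at 6 and 12 spacings (Tac2), 1 at 4 and 20 spacings (Uts2) and 1 to 5 when each library was left out. It was Uts2 alone without SCI 3, Calca was called only without SCI 2 or SCI_AD 4, and Ahnak2 and Slc18a3 joined the 3 genes without SCI 2. Without SCI_AD 1 Chil1 (2.11) was called there too. In white matter it was called for 0 genes at 4 and 20 spacings and for 1 to 5 when each library was left out, with 5 without SCI 1 (Chil1, Serpina3n, Klk8, Lcn2 and Klk6). Ahnak2, Slc18a3, Lcn2 and Klk6 are named after their values were seen.

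Lists of genes rest on the preset correlation. With an estimated correlation, and with fry, 0 lists were called in whole sections, remaining grey matter, superficial dorsal horn, white matter, meninges and nerve roots, and lesion regions. Leaving out each library gave 10 to 16 lists in whole sections at the preset correlation. Near the lesion an estimated correlation left 3 lists in remaining grey matter and 6 in white matter, and 0 in both for the difference between groups. Of 7477 values of named genes under alternatives 7339 kept their side of the threshold, 64 no longer passed, 68 newly passed and 6 reversed, while 85 in all took another sign, most of them without a call in either setting. Of 396 values of lists the numbers were 139, 196, 60 and 1, with 12 of another sign. All 60 values of single region shares stayed without a call, 6 with another sign.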

Other observations

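The tests on Xist depth and Y-linked genes, on matching pieces of tissue, on ependymal genes, on the share of neurons and on remaining grey matter near the lesion were chosen only after their results were seen.

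Genes that rose near the lesion may include RNA that spread from lesion spots, because the lesion holds more of most of them. In remaining grey matter 25.2% of the 1050 genes that rose, and in white matter 36.3% of the 984, had a higher CPM near the lesion than inside it. Of these, 149 and 254 genes were higher in every library. This argues against spread at the mean level of the lesion regions as the whole cause. That level pools the core and the border, so it cannot decide on spread from the border alone. For genes that stay below their level in the lesion, spread remains open. Their excess near the lesion as a share of their excess in the lesion was taken for the 475 genes in remaining grey matter and 361 in white matter with at least 50 CPM in the lesion and at least 2 times their far level there. The median was 20.1% with quartiles of 16.1% and 25.8%, and 19.3% with quartiles of 14.5% and 24.4%, so that the upper quartile was 1.6 and 1.68 times the lower one. Spread was predicted to give a ratio under 2, so both ratios met that prediction without showing spread. Gpnmb and Lyz2 belong to the genes below their level in the lesion. A lower share of neurons is argued against as the whole cause of the rises in remaining grey matter. Phagocyte and endothelial genes there moved apart by a median log2 of 1.169. Whether neurons were fewer near the lesion was not tested. The design gives no group for distance, so no biological explanation was tested.

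Xist was almost missing from the middle pieces of SCI_AD 3 and SCI 1, with 3 and 8 UMIs where the lowest share in the other 19 pieces would give 170 and 296. Depth cannot explain this, with a larger Poisson probability of 1.35e-68, nor can tissue with a Y chromosome, since 4 Y-linked genes reached 0 CPM at most in both pieces. Xist was not alone: Gm47283 stood at 4.19 and 3.74 CPM there against 31.2 to 118 CPM in the other 19, and lesion regions held 38.9% and 36.9% of the spots against 24.6% at most. A cord with a single X chromosome cannot be told apart from another loss of Xist. Genes that escape X inactivation lay 0.054 (median log2) above inactivated genes in SCI_AD 3 and -0.227 from them in SCI 1, with an error of 0.166 that leaves this open. Both libraries carry title number 3, and pieces at the same position in libraries of the same title number resembled each other. The mean correlation was 0.351. Of all assignments of positions within title numbers 1, the real one, was as high, the highest other was 0.299, and between different title numbers the mean was 0.104. SCI_AD 3 and SCI 1 had the highest correlation, at 0.473. The lesion core, as used for distances, held 74, 236 and 14 spots in the upper, middle and lower pieces of SCI_AD 3. In those of SCI 1 it held 70, 203 and 13 spots. Neighbouring sections of the same cords in libraries of both groups would give such matches, but the labels do not state this.

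In remaining grey matter a split set SCI_AD 2, SCI 1, SCI 3 and SCI_AD 4 against the other 3 libraries. It called 603 genes, 266 higher and 337 lower, against 0 for the real groups, which may reflect a structure of the samples. This split was picked because it had the most calls of all 35. The p-values of lists given for it therefore describe the split and do not test it. In whole sections this split called 0. Depth does not account for all of it, since 97 of 5148 genes were called after the sums were thinned to the same total. The level of the sections in the cord, as told by the ependymal cells of the central canal, stays open. A single ependymal gene (1) separated the libraries in whole sections, with SCI 1 at a mean log2 CPM of 3.11 against 2.81 in SCI_AD 3 on the other side. The ependymal list was nevertheless lower in the 4 libraries, with 0 of 12 genes positive in remaining grey matter, 7 of them among the 603 (camera adjusted p = 7.83e-19, and 0.157 with an estimated correlation). Lists of other cells moved there too, with myelin genes positive in 16 of 16 (adjusted p = 6.58e-21, and 0.157 with an estimated correlation), synaptic genes in 3 of 18 (adjusted p = 2.47e-07, and 0.194 with an estimated correlation) and cholinergic genes in 10 of 13 (adjusted p = 0.000688, and 0.235 with an estimated correlation). The makeup of the sections followed the same split. Remaining grey matter held 9.45% to 18.5% of the spots in the 4 libraries and 22.5% to 29.1% in the other 3. White matter held 13.4% to 18.4% in the 4 and 11.5% to 12.7% in the other 3. Whether this accounts for the calls, or whether the tissue inside the regions differs, was not tested. With the level of ependymal genes as a covariate 0 genes were called between the real groups. The design gives no biological group that follows this split.

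Chance is argued against, but not excluded, for the number of genes that differ near the lesion. The exchanges used for this cannot give a share below 1 of 64. They also take the libraries as independent, which those of the same title number may not be. Of the 64 exchanges of near and far within libraries 1, the real one, gave 2032 genes in remaining grey matter, with 1140 as the highest other, and 1 gave 1872 in white matter, with 276 as the highest other. Chance cannot be excluded for the 12 lists shifted in whole sections, since 26 of the 35 splits gave as many and the highest other gave 21. Between the groups the real count was 0 genes by edgeR's quasi-likelihood test. A count of 0 is reached by all 35 splits by construction, so this number says nothing about chance. The highest other was 6 in whole sections (330 at an unadjusted p under 0.05, 0 by DESeq2), 603 in remaining grey matter (287, and 0 by DESeq2) and 17 in superficial dorsal horn (305, and 0 by DESeq2). It was 70 in white matter (638, and 20 by DESeq2), 3 in meninges and nerve roots (494, and 5 by DESeq2) and 2 in lesion regions (644, and 20 by DESeq2). For the interaction of grey and white matter it was 177 (372 at an unadjusted p under 0.05, DESeq2 not run), and for Moran's I by limma, where the 35 splits say as little, it was 0 (103 at an unadjusted p under 0.05).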
